A study of Homo sapiens with 7 samples.

How the data were processed

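The series holds 7 expression arrays of MCF-10A cells, 3 with a scrambled control hairpin (shControl) and 4 with a hairpin against Brit1 (shBrit1). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted and biotinylated cRNA was prepared with the Illumina TotalPrep kit. The deposited table of bead signals gives, per the file headers, an intensity and a detection p-value for each probe and array. These intensity values are linear and differ in their quartiles between arrays (median 75.9 to 87.6), so no normalization between arrays had been applied, and the scanner software and its settings are not given in the sources used here. The detection p-value, deposited by the authors beside each signal, moves in steps of 1 over 1374 negative control probes. It followed the signal of its own array closely (Spearman's rho across probes -0.998 to -0.999) and of no other array as closely. The authors also deposited log2 values of the same arrays. These correlated with the log2 signal of their own array at 0.999 or more across probes and had the same median of 6.37 on every array. Their sorted values differed between arrays by at most 0.000887 log2, so they were quantile-normalized on the log2 scale. Their direction is that of the signal, they are not centred, and the tool that made them is not given in the sources used here. They were used as an alternative only. One line of the signal table held a fragment of annotation text with no values and was left out, leaving 48701 probes.

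Probe names came from the platform annotation supplied with the data, checked through gene identifiers against the RefSeq table of GRCh38.p14, which changed 0 names and was otherwise used only for the order of genes on chromosomes. Of the 48701 probes 24782 had 1 gene symbol, 0 had several and 23919 had none, and the unnamed probes entered the counts of probes but no statement on genes. The targeted gene was not analysed here.

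Background correction and normalization used neqc of limma 3.58.1 in R 4.3.3 (normexp with the negative control mean and SD inferred from the detection p-values, an offset of 16, then quantile normalization and log2). Probes with a detection p-value under 0.05 on at least 3 of the 7 arrays were kept without use of the groups (17967 probes, 14165 of them named, for 12372 genes). Groups were compared with lmFit and eBayes without trend, two-sided, with Benjamini-Hochberg adjustment over the kept probes, and adjusted p-values under 0.05 were called. For gene lists and named genes 1 probe per gene was used, the one with the highest mean over all arrays. A gene not detected on any array of a group (detection p-value 0.05 or above) is given as a bound, the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest value among detected probes and the probe's own value, all as normalized log2 values. The fold of a gene detected on only some arrays of a group is uncertain, and their number is given. A fold without "at least" is 2 to the power of the log2 difference.

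Named genes followed a rule fixed before the data were examined. It took the 10 higher and 10 lower genes with the largest log2 difference among those called, with a symbol other than a locus number and with every array of one group on the same side of every array of the other, and up to 4 members with the smallest p-value of each gene list. The 35 gene lists were also written before the data were examined. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at the estimated correlation, and with fry, adjusted over lists. The list of genes next to the targeted locus had 3 measured genes and was not tested. Where a gene has several kept probes, the other probes were checked for a call in the opposite direction, and among the genes named only RPL13, which is not used further, had one.

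The fit was tested on simulated data with the spread of the real probes. For the comparison of shBrit1 with shControl over 17967 probes, 22.0% of 50 probes changed by 0.5 log2 were recovered, 82.0% of 50 changed by 1, 98.0% of 50 changed by 2 and 100% of 50 changed by 3, with 6 false calls. The simulated changes were few beside the 9669 probes called in the data, where the adjustment is therefore less strict. These rates thus do not give the share of real changes that was found. For lists over 12372 genes, 5 of 5 lists shifted by 0.5 log2 were recovered and 0 of 27 untouched lists were called. The simulated genes varied independently of each other, so the list result does not test the preset correlation of 0.01. In the real data the estimated correlation ran from -0.10 for immune cell markers to 0.86 for inflammatory genes.

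Alternatives fixed before the data were examined were no background correction, normexp without negative controls and an offset of 50, median scaling or cyclic loess in place of quantile normalization, an offset of 50, no filter or detection at p under 0.01 on all 7 arrays, eBayes with trend and robust settings, array weights, the authors' values, shControl replicates 1 and 2 averaged as 1 sample (their descriptions share a letter), the replicate number as a block, leaving out each array, Bonferroni adjustment, and for lists the estimated correlation and the mean of all probes of a gene. Leaving out probes with a failed signal and list counts without shControl replicate 3 were added after the data had been seen. Controls 1 and 2 differed with an SD of 0.19 log2 across probes, within the 0.16 to 0.23 of pairs of shBrit1 arrays. They were counted as separate samples, but this spread cannot show whether they came from 1 culture. When they were averaged as 1 sample, 4423 probes were higher and 4416 lower. No chip or scan information was used here, so a chip effect that follows the groups cannot be told apart from them.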

Results

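Gene expression was measured in MCF-10A cells, a non-transformed human mammary epithelial line, that stably carried a short hairpin RNA against Brit1 or a scrambled control hairpin, both delivered by lentivirus. Brit1 takes part in the DNA damage response, and the study set out to profile cells in which a gene of homologous recombination was knocked down. Total RNA was taken 48 h after seeding and hybridised to 1-colour bead arrays, with 3 arrays of control cells (shControl) and 4 arrays of knockdown cells (shBrit1), described by the submitters as biological replicates. Between 16537 and 17343 of 48701 probes had a detection p-value under 0.05 on an array, and 17967 probes on which at least 3 of the 7 arrays passed that limit were tested. The number of arrays limits the precision of every value. The targeted gene was not analysed here, so the depth of the knockdown was not checked and the group names rest on the labels.

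The difference between knockdown and control cells was broad and went in both directions. Of the 17967 probes, 4829 were higher and 4840 were lower in shBrit1 (limma, adjusted p under 0.05), and 2960 of these differed at least 2-fold, 1442 upwards and 1518 downwards. Median scaling in place of quantile normalization gave 3125 higher and 6554 lower, and 1868 probes differed at least 2-fold with no background correction. Arrays of different groups correlated at 0.930 to 0.937 across the tested probes, and the 4 shBrit1 arrays at 0.995 to 0.998 with each other. Among the controls, replicates 1 and 2 differed with an SD of 0.192 log2 across probes, and replicate 3 stood apart from them with SDs of 0.531 and 0.510. Without shControl replicate 3, limma called 5573 probes higher and 5821 lower, of which 4744 and 4731 were shared with the calls on all arrays.

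SELENOP, which encodes a plasma selenium carrier, was not detected on any shControl array and was at least 53.7-fold higher in shBrit1, with a mean of 10.86 ± 0.06 (SD, n = 4) on the log2 scale and an adjusted p of 5.37e-09. PDK4, a kinase that restrains pyruvate dehydrogenase, and ADH1A, an alcohol dehydrogenase, were also undetected in the controls and were at least 47.3-fold and at least 39.1-fold higher. The ADH1A value is uncertain because close paralogs of this gene could bind the same probe. DCN, the gene of the matrix proteoglycan decorin, rose from 6.78 ± 0.16 (SD, n = 3) to 12.61 ± 0.06 (SD, n = 4), a 56.5-fold difference. FBXO32, a muscle atrophy-related ubiquitin ligase subunit, was 49.8-fold higher (log2 difference 5.64, SE 0.14), and MAOA, which oxidises monoamines, was 42.4-fold higher (log2 difference 5.40, SE 0.34). Without shControl replicate 3 MAOA was 60.7-fold higher. The glycoprotein gene GPNMB rose 39.8-fold and the interferon-inducible GTPase gene GBP2 30.2-fold. ZNF467, a zinc finger gene detected on 1 of the 3 control arrays, rose 28.9-fold, and the metalloproteinase gene MMP7 rose 23.2-fold. The folds of genes near background in the controls, bounds included, hold for this background correction. With the authors' values the log2 difference was 4.58 for SELENOP, 4.42 for PDK4, 4.18 for ADH1A, 3.97 for GBP2 and 3.51 for ZNF467. With these values DCN, FBXO32, MAOA and GPNMB, at 4.94 or higher in each alternative, lay above SELENOP. The adjusted p of these 10 genes was at most 3.04e-06. That every shBrit1 array lay above every shControl array in each of them was a condition of their choice. The groups did not overlap in 9247 of all 9669 changed probes.

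SCG5, a chaperone of neuroendocrine secretory granules, fell from 9.74 ± 0.85 (SD, n = 3) to 5.31 ± 0.07 (SD, n = 4), or 21.7-fold. LIPG, the gene of endothelial lipase, was 15.9-fold lower (log2 difference -3.99, SE 0.10), and F3, the gene of tissue factor, which starts coagulation, was 15.4-fold lower (log2 difference -3.94, SE 0.09). ANO1, a calcium-activated chloride channel gene detected on 2 of the 4 shBrit1 arrays, was 15.1-fold lower. The lipoprotein receptor gene LRP8 fell 13.1-fold, the matrix glycoprotein gene THBS1 12.7-fold, and FST, whose product binds activin, 11.9-fold. ANGPTL4, an inhibitor of lipoprotein lipase, was 11.2-fold lower, FGFBP1, a carrier of fibroblast growth factors, 10.1-fold lower, and GPAT3, an enzyme of triglyceride synthesis, 8.67-fold lower and detected on 3 of the 4 shBrit1 arrays. With the authors' values the log2 differences of genes near background in shBrit1 were smaller. They were -3.22 for SCG5, -2.85 for LIPG, -2.67 for ANO1, -2.88 for LRP8 and -2.04 for GPAT3. With these values F3, at -3.64, lay below SCG5. So did THBS1, ANGPTL4 and FGFBP1, which were at -3.48, -3.34 and -3.24 or lower in each alternative. The adjusted p of these 10 genes was at most 2.28e-05. Some of these folds depended on shControl replicate 3. Without it SCG5 was 15.4-fold lower, close to LIPG at 15.3-fold, FST 9.16-fold lower and GPAT3 11.5-fold lower.

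**Figure D1:**
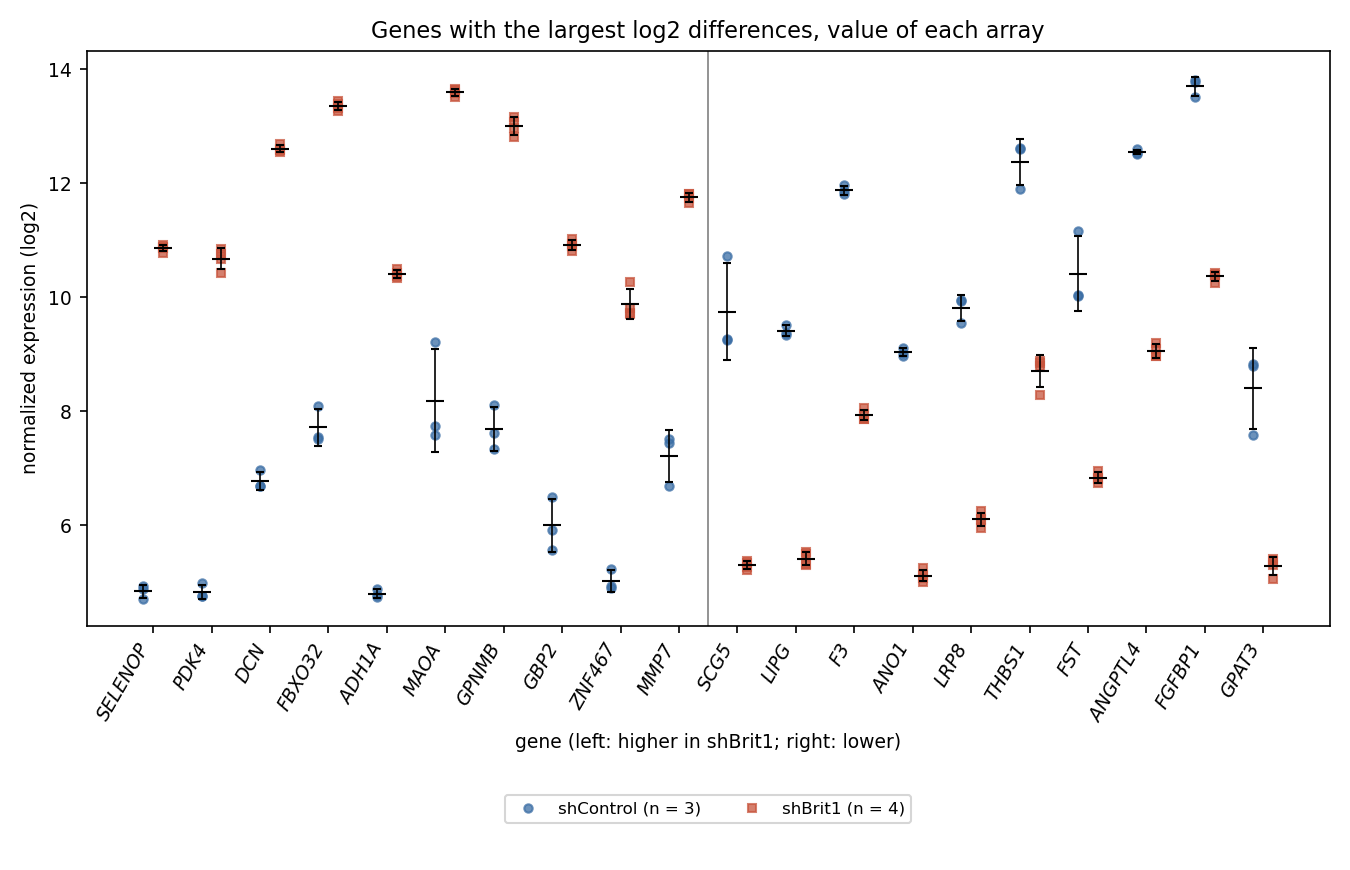
Normalized log2 expression (vertical axis) of the 10 genes with the largest rise and the 10 with the largest fall in shBrit1 (horizontal axis). Circles are the 3 shControl arrays and squares the 4 shBrit1 arrays, with the mean and SD in black. No gene's groups overlap, which was a condition of the choice. DCN has a mean of 6.78 in shControl and 12.61 in shBrit1, and SCG5 of 9.74 and 5.31.

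Of all 12372 genes tested, 3653 were higher and 3718 lower in shBrit1, shares against which the counts within a list can be read. Of 34 gene lists with at least 5 measured genes, 8 were higher and 14 lower by camera with a preset correlation between genes of 0.01. With the correlation estimated from the data, camera called 0 lists at an adjusted p under 0.05 and 9 at an unadjusted p under 0.05, and the lowest adjusted p was 0.0525. Without shControl replicate 3 it called 7 lists. These were DNA replication and interferon response (adjusted p = 0.0259 each), mitosis and ribosome biogenesis (0.0295 each), and homologous recombination, cholesterol synthesis and inflammatory genes (0.0439 each). The size of the estimated correlation does not alone account for the lost calls. For ribosome biogenesis on all arrays it was 0.0067, under the preset 0.01. The unadjusted camera p of that list still went from 1.37e-09 to 0.00155. The rotation test fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, called 28 lists.

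Genes of cell division fell nearly as a block. Of 39 mitosis genes 38 were lower and 0 higher (38 lower when adjusted over the list alone), with a median log2 difference of -1.50 and a camera adjusted p of 1.96e-13 (adjusted p = 0.172 with an estimated correlation). The mitotic kinase gene AURKA was 3.06-fold lower (log2 difference -1.61, SE 0.08), the transcription factor gene FOXM1 3.87-fold lower and the kinetochore gene SPC25 4.59-fold lower. On shControl replicate 3 the medians of the mitosis and DNA replication lists stood at -0.34 and -0.25 against the other controls, and without that array 39 and 38 of their genes were lower. Of 40 DNA replication genes 36 were lower and 1 higher (37 lower and 1 higher when adjusted over the list alone), with a median of -1.53 and an adjusted p of 2.33e-13 (adjusted p = 0.127 with an estimated correlation). UHRF1, which maintains DNA methylation at replication, fell 6.28-fold, the replication factor gene CDC45 4.91-fold and the clamp loader subunit RFC3 4.52-fold. In the list of E2F1 targets 9 of 11 genes were lower and 1 higher, with the same counts when adjusted over the list alone (adjusted p = 0.000279, and adjusted p = 0.127 with an estimated correlation), among them CCNE2 (7.78-fold lower), the phosphatase gene CDC25A (7.49-fold lower) and E2F1 itself (5.03-fold lower). Condensin and cohesin genes were lower in 11 of 17 cases and higher in 1 (14 lower and 2 higher when adjusted over the list alone), with an adjusted p of 0.000976 (adjusted p = 0.215 with an estimated correlation), SMC2 falling 3.71-fold and NCAPG 3.83-fold. In the list of other microcephaly genes with SET, 9 of 11 were lower and 1 higher (10 lower and 1 higher when adjusted over the list alone), with an adjusted p of 0.000976 (adjusted p = 0.172 with an estimated correlation), including the centriole gene STIL (4.23-fold lower) and the spindle pole genes ASPM (3.11-fold lower) and WDR62 (4.46-fold lower, detected on 2 of the 4 shBrit1 arrays).

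Several lists of DNA repair genes were lower. Among homologous recombination genes 20 of 28 were lower and 1 higher, with the same counts when adjusted over the list alone, a median of -0.83 (-0.79 with 1 undetected gene at its bound) and an adjusted p of 5.97e-05 (adjusted p = 0.180 with an estimated correlation). The median of this list was lower on shControl replicate 3 than on the other controls by a log2 difference of -0.34, and without that array 23 genes were lower, with an adjusted p of 4.38e-06 (adjusted p = 0.0439 with an estimated correlation). The helicase gene BLM was 4.39-fold lower (log2 difference -2.13, SE 0.12), RAD54L 3.91-fold lower, RAD51AP1 3.07-fold lower and XRCC3 3.01-fold lower. In the Fanconi anaemia pathway 8 of 14 genes were lower and 2 higher (9 lower and 2 higher when adjusted over the list alone), with an adjusted p of 0.00949 (adjusted p = 0.127 with an estimated correlation). FANCB fell 4.62-fold and FANCI 3.05-fold, whereas FANCE rose 2.73-fold. Of 19 DNA damage checkpoint genes 12 were lower and 1 higher (12 lower and 2 higher when adjusted over the list alone), with an adjusted p of 0.0112 (adjusted p = 0.189 with an estimated correlation), including TIPIN (4.65-fold lower) and TIMELESS (3.28-fold lower). Non-homologous end joining was not called by camera (adjusted p = 0.104) and was called lower by fry (adjusted p = 0.000158). In this list 6 of its 13 genes were lower and 1 higher (7 lower and 1 higher when adjusted over the list alone), and PRKDC was 2.34-fold lower. Mismatch and excision repair split into 8 higher and 11 lower of 32, with the same counts when adjusted over the list alone (camera adjusted p = 0.548, fry adjusted p = 0.00202, lower), and into 4 higher and 15 lower with median scaling. Targets of p53 also split, with 12 higher and 9 lower of 30 and the same counts when adjusted over the list alone (camera adjusted p = 0.425, fry adjusted p = 0.0826). Without shControl replicate 3 there were 15 higher and 8 lower (camera adjusted p = 0.312, fry adjusted p = 0.00230, higher). TP53INP1 rose 3.30-fold and SESN1 2.84-fold, while TIGAR fell 4.47-fold and AEN 2.88-fold.

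Lists of biosynthesis and growth signalling were lower as well. Of 22 ribosome biogenesis genes 20 were lower and 0 higher, with the same counts when adjusted over the list alone, a median of -1.26 and an adjusted p of 1.55e-08 (adjusted p = 0.0525 with an estimated correlation). RRS1 fell 6.48-fold, LYAR 6.39-fold and NOP56 4.81-fold. Of 27 genes of cholesterol and fatty acid synthesis 22 were lower and 2 higher, unchanged when adjusted over the list alone (adjusted p = 5.97e-05, and adjusted p = 0.0687 with an estimated correlation). HMGCS1, an early enzyme of the sterol pathway, was 6.29-fold lower, IDI1 4.63-fold lower and the desaturase gene SCD 3.35-fold lower. Feedback genes of MAP kinase signalling and ligands of the epidermal growth factor receptor were lower in 15 of 24 cases and higher in 3, with the same counts when adjusted over the list alone (adjusted p = 0.000740, and adjusted p = 0.262 with an estimated correlation). The median of this list was 0.41 higher on shControl replicate 3 than on the other controls, and without that array it went from -0.74 to -0.64, with an adjusted p of 0.00267 (adjusted p = 0.112 with an estimated correlation). FOSL1 fell 6.88-fold, ETV5 5.62-fold, and the phosphatase gene DUSP6, not detected on any shBrit1 array, at least 5.20-fold. Endoplasmic reticulum chaperones were lower in 14 of 19 cases and higher in 1 (15 lower and 1 higher when adjusted over the list alone), with an adjusted p of 0.000740 (adjusted p = 0.115 with an estimated correlation), SDF2L1 falling 3.33-fold and HYOU1 2.77-fold. Hypoxia and glycolysis genes were lower in 13 of 30 cases and higher in 3 (15 lower and 3 higher when adjusted over the list alone), with an adjusted p of 0.0197 (adjusted p = 0.127 with an estimated correlation). With median scaling 22 were lower and 2 higher. The glycolytic enzyme gene HK2 was 3.98-fold lower and MXI1, a transcriptional repressor, 2.94-fold higher. The integrated stress response list was lower in 14 of 25 cases and higher in 3, with the same counts when adjusted over the list alone (adjusted p = 0.0228, and adjusted p = 0.322 with an estimated correlation). Its median on shControl replicate 3 stood at -0.39 against the other controls. Its members parted: the serine synthesis gene PSAT1 fell 5.77-fold and TRIB3 4.91-fold, while the stress-induced regulators NUPR1 and DDIT3 rose 5.19-fold and 5.06-fold.

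**Figure D2:**
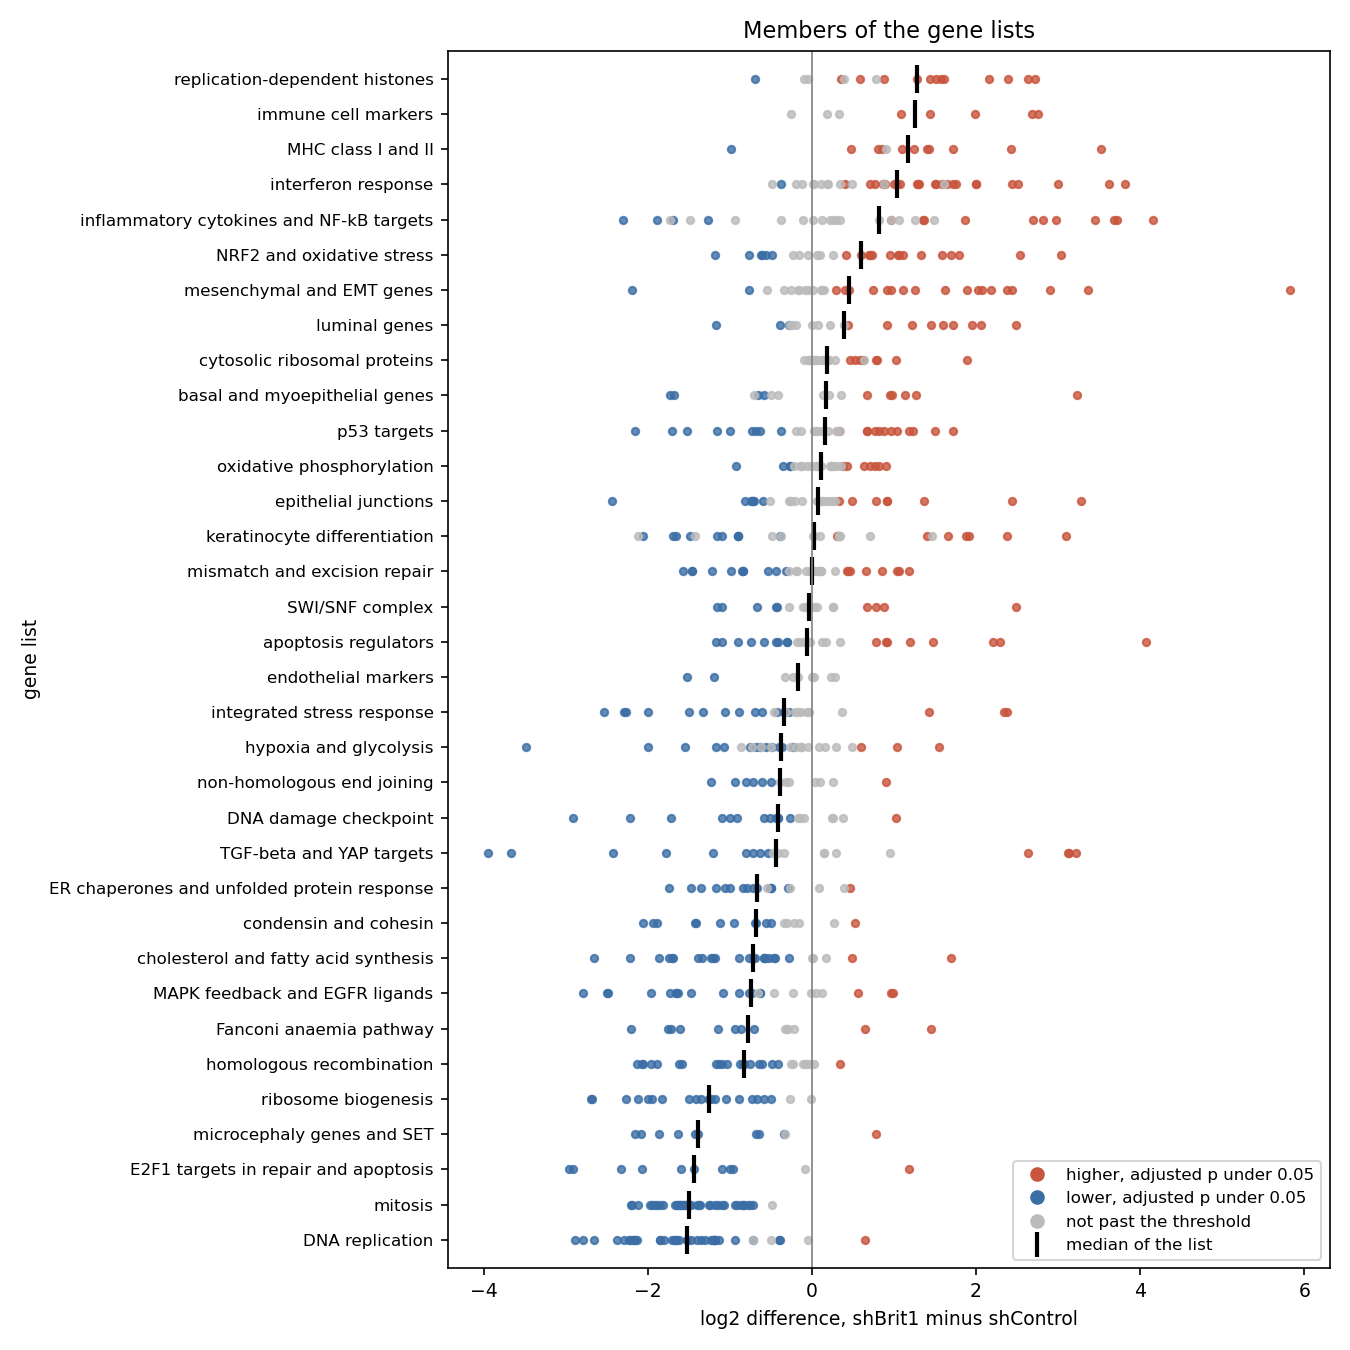
Log2 difference between shBrit1 and shControl (horizontal axis) of each measured member of 34 gene lists (vertical axis, sorted by median). Each point is a gene, red when higher and blue when lower at an adjusted p under 0.05 and grey otherwise, and black bars are medians, which run from -1.53 for DNA replication to 1.27 for replication-dependent histones.

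Interferon-inducible and antigen presentation genes rose. In the interferon response list 24 of 37 genes were higher and 1 lower, with the same counts when adjusted over the list alone, a median of 1.04 and an adjusted p of 0.000159 (adjusted p = 0.545 with an estimated correlation). IFI44L was 12.2-fold higher (log2 difference 3.61, SE 0.12), IFITM2 3.99-fold higher, and MX1, detected on 1 of the 3 control arrays, 2.83-fold higher. The same list was also 1.03 higher by its median on shControl replicate 3 than on the other controls, and without that array 30 genes were higher and 0 lower, with an adjusted p of 4.35e-10 (adjusted p = 0.0259 with an estimated correlation). Genes of the major histocompatibility complex classes I and II and their partners were higher in 10 of 12 cases and lower in 1 (11 higher and 1 lower when adjusted over the list alone), with an adjusted p of 0.000675 (adjusted p = 0.172 with an estimated correlation) and a median 0.21 higher on shControl replicate 3 than on the other controls. B2M, the common light chain of class I, rose 2.69-fold, HLA-E 2.63-fold and HLA-DMA 5.39-fold. Values of single class I genes are uncertain because of their close similarity. Inflammatory cytokines and NF-kB targets were not called on all arrays by camera (adjusted p = 0.134) or fry (adjusted p = 0.348). Of 31 genes 11 were higher and 4 lower (10 higher and 3 lower when adjusted over the list alone). With median scaling camera called the list higher (adjusted p = 0.00928). SOD2 was 6.50-fold higher and PTGS2 4.93-fold lower. CFB, a complement component gene detected on 2 of the 3 control arrays, was 17.8-fold higher, and 30.6-fold higher without shControl replicate 3. This list's median was 2.14 higher on shControl replicate 3 than on the other controls, and without that array 21 genes were higher and 6 lower, with an adjusted p of 0.000137 (adjusted p = 0.0439 with an estimated correlation). Markers of immune cells were higher in 5 of 8 measured cases and lower in 0 (6 higher when adjusted over the list alone), with an adjusted p of 0.00453 (adjusted p = 0.127 with an estimated correlation), while 12 other markers on the array were left out as not detected on enough arrays. With no filter on dim probes, 20 markers were measured and the list was no longer called (adjusted p = 0.0727). LAPTM5, undetected in the controls, was at least 5.98-fold higher, CD14, detected on 2 of the 3 controls, 6.39-fold higher, the lysosomal CD68 3.96-fold higher and the receptor gene CSF1R 2.70-fold higher.

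**Figure D3:**
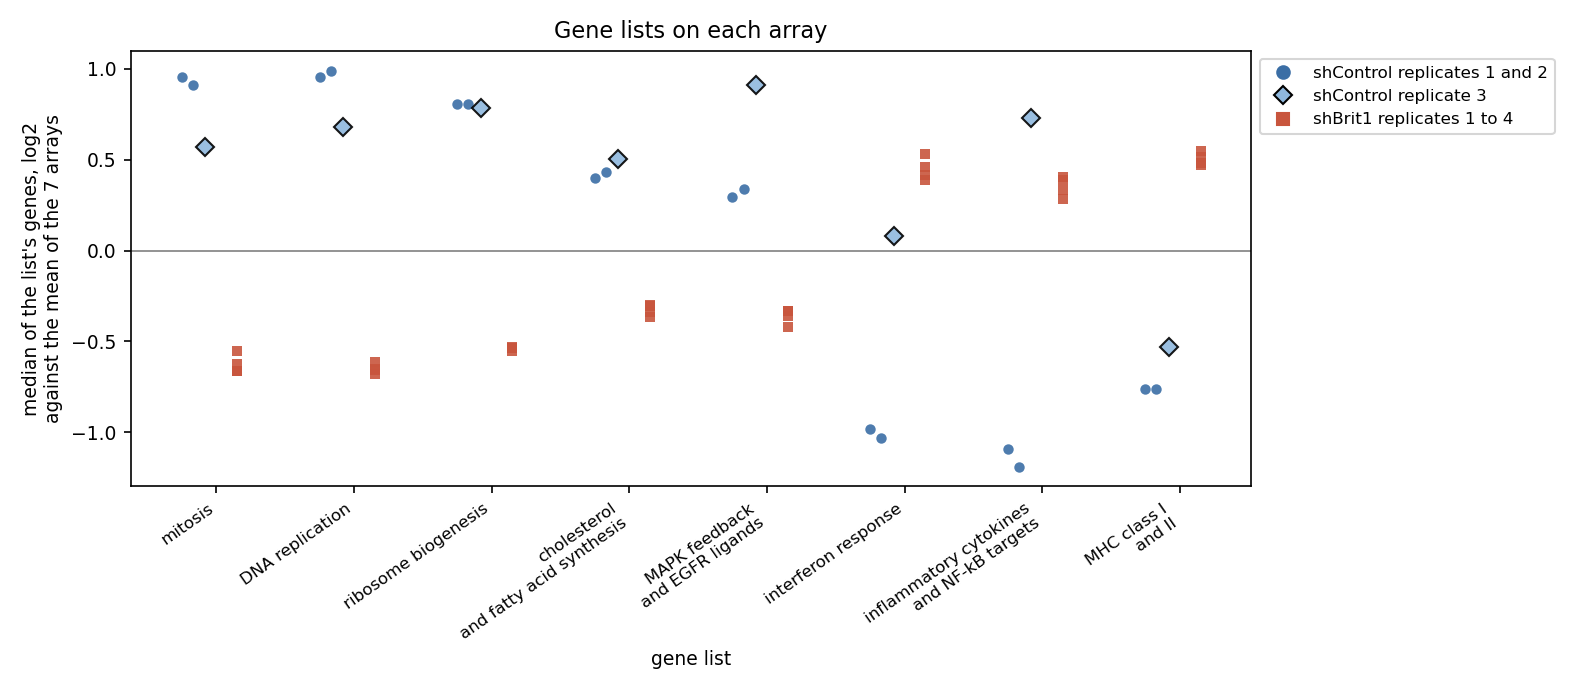
Median over the genes of 8 lists (horizontal axis) on each array, as log2 against each gene's mean over the 7 arrays (vertical axis). Circles are shControl replicates 1 and 2, diamonds shControl replicate 3 and squares the 4 shBrit1 arrays; in the inflammatory list shControl replicate 3 lies at 0.73, above the shBrit1 arrays at 0.29 to 0.41, and replicates 1 and 2 lie at -1.09 and -1.19.

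Markers of cell state changed in several directions. Of 31 mesenchymal genes 18 were higher and 2 lower, with the same counts when adjusted over the list alone (adjusted p = 0.00178, and adjusted p = 0.127 with an estimated correlation). Besides DCN, the transcription factor genes ZEB2, detected on 2 of the 3 control arrays, and TWIST1 were 5.42-fold and 4.20-fold higher and ACTA2, a smooth muscle actin gene, 3.07-fold higher. Luminal genes were higher in 9 of 19 cases and lower in 3, with the same counts when adjusted over the list alone (adjusted p = 0.0333, and adjusted p = 0.347 with an estimated correlation), including GATA3 (5.60-fold), ELF3 (3.87-fold) and ERBB3 (3.29-fold). Their median was 0.17 lower on shControl replicate 3 than on the other controls, and without that array 9 genes were higher and 7 lower, the median went from 0.39 to 0.05 and the list had an adjusted p of 0.229. Basal and myoepithelial genes split into 6 higher and 4 lower of 16, or 6 and 6 when adjusted over the list alone (camera adjusted p = 0.654, fry adjusted p = 0.312), with MME 9.40-fold higher and OXTR, undetected in shBrit1, at least 3.11-fold lower. Epithelial junction genes (8 higher and 7 lower of 29, or 8 and 6 when adjusted over the list alone, adjusted p = 0.818) and keratinocyte differentiation genes (8 higher and 10 lower of 31, with the same counts when adjusted over the list alone, adjusted p = 0.862) were not called by camera. Fry called the keratinocyte list lower (adjusted p = 0.00107) and did not call the junction list (adjusted p = 0.0961). Without shControl replicate 3 it called both higher (adjusted p = 0.00430 and 0.00938). The medians of the basal, junction and keratinocyte lists, 0.17, 0.08 and 0.02, changed sign with median scaling, to -0.34, -0.29 and -0.11. The junction gene TJP3 was nevertheless 9.67-fold higher and the connexin gene GJB2 5.42-fold lower. Endothelial markers were lower in 2 of 9 cases and higher in 0, with the same counts when adjusted over the list alone (camera adjusted p = 0.376, fry adjusted p = 0.00104, lower).

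Replication-dependent histone genes were higher in 12 of 17 cases and lower in 1, with the same counts when adjusted over the list alone, a median of 1.27 and an adjusted p of 0.00159 (adjusted p = 0.272 with an estimated correlation). H2AC6 rose 4.45-fold and H1-2 6.61-fold, values that are uncertain for single genes of this nearly identical family, whose median was 0.48 higher on shControl replicate 3 than on the other controls. NRF2 targets were higher in 15 of 27 cases and lower in 6, with the same counts when adjusted over the list alone (adjusted p = 0.0362, and adjusted p = 0.347 with an estimated correlation), with the ferritin gene FTL 5.78-fold and ALDH3A1 8.18-fold higher. The adjusted p of this list was 0.0682 without shControl replicate 3, and with median scaling 11 genes were higher and 9 lower, with a median of 0.23 in place of 0.60. Cytosolic ribosomal protein genes were higher in 8 of 27 cases and lower in 0 (5 higher when adjusted over the list alone), with a median of 0.18 and an adjusted p of 0.0248 (adjusted p = 0.262 with an estimated correlation). The share higher was close to that of all tested genes, where 3653 of 12372 were higher and 3718 lower. RPL37 was 3.70-fold and RPS23 2.04-fold higher. Without shControl replicate 3 the adjusted p was 0.0739, and with median scaling in place of quantile normalization 4 of these genes were higher and 10 lower, with a median of -0.17.

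The remaining lists were not called by camera, and of these fry called apoptosis regulators (adjusted p = 0.00122) and oxidative phosphorylation (adjusted p = 0.0381) higher. In the TGF-beta and YAP list 4 genes were higher and 9 lower of 20, or 5 and 9 when adjusted over the list alone (adjusted p = 0.504). Besides the fall of F3, ID2, detected on 2 of the 3 control arrays, and ID3, inhibitors of DNA binding known as targets of bone morphogenetic proteins, rose 8.78-fold and 8.69-fold, and SMAD6, undetected in the controls, rose at least 7.14-fold. Apoptosis regulators split into 8 higher and 9 lower of 24, with the same counts when adjusted over the list alone (adjusted p = 0.654). BMF, undetected in the controls, was at least 3.30-fold higher. TNFSF10, the gene of a death ligand detected on 1 of the 3 control arrays, was 16.9-fold higher, and 24.7-fold higher without shControl replicate 3. Of 27 oxidative phosphorylation genes 7 were higher and 4 lower, or 6 and 4 when adjusted over the list alone (adjusted p = 0.328). Of 17 SWI/SNF genes 4 were higher and 5 lower, with the same counts when adjusted over the list alone (adjusted p = 0.966), with SMARCD3 5.62-fold higher and PBRM1 2.23-fold lower. In some of these lists the measures differ in sign. The median was -0.03 and the mean 0.07 for SWI/SNF genes, and -0.06 and 0.34 for apoptosis regulators. The TGF-beta and YAP list, with a median of -0.44, pointed upwards by fry without being called (adjusted p = 0.704). The median of that list was 0.41 higher on shControl replicate 3 than on the other controls and went to -0.13 without that array, where fry called it higher (adjusted p = 0.00177). The median of oxidative phosphorylation genes went from 0.12 to -0.25 with median scaling, and that of p53 targets from 0.16 to -0.14. For SWI/SNF genes median scaling gave 3 higher and 10 lower, with a median of -0.54. Without shControl replicate 3 fry called this list lower (adjusted p = 0.0389). Of the genes next to the targeted locus only 3 were measured, too few for the list test. DEFB1, a beta-defensin gene, was 17.4-fold higher (log2 difference 4.12, SE 0.12), AGPAT5 was 2.20-fold lower, and CSMD1, detected on 2 of the 3 control arrays, differed by 0.10 (SE 0.11, adjusted p = 0.460).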

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

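In the 4 shBrit1 arrays, 9 of 157 tested results had 1 array far from the other 3 by Dixon's ratio of the gap to the range, and chance flags about 1 in 20. The array that stood apart was replicate 1 for THBS1 (ratio 0.860, 8.28 against a mean of 8.84 on the others), FANCB (0.840, 5.20 against 5.37), MME (0.916, 10.29 against 10.54), NOP56 (0.878, 11.86 against 11.61) and ATP5MC1 (0.933, 11.23 against 10.96). It was replicate 3 for FGFBP1 (0.856, 10.25 against 10.40) and TJP3 (0.875, 9.09 against 9.24), replicate 2 for RFC3 (0.875, 7.04 against 7.13) and replicate 4 for FANCI (0.901, above a mean of 8.83 on the others). Groups of 3 arrays were not tested in this way.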

How the results depend on the processing

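The alternative without failed probes was chosen after the data had been seen and gave 4828 probes higher and 4840 lower. Among 3042 comparisons of 154 named genes with the alternatives, 0 reversed, 3035 stayed on their side of the threshold, 3 lost their call and 4 gained one. The 3 losses came with median scaling (RPL4 at 0.24, UQCRC1 at 0.20 and NDUFB5 at 0.25) and the 4 gains were EGFL7 and ERG with array weights and without shControl replicate 3. Median scaling moved the median of all probes from -0.01 to -0.16 and called 3125 probes higher and 6554 lower, so 32.3% of its calls were higher against 49.9% with quantile normalization; changes are thus relative to the centre of each array. Probes at least 2-fold numbered 1868 with no background correction, 1947 with normexp without negative controls and 1866 with the authors' values, against 2960, as these leave background or an offset in the signal of dim probes. Bonferroni adjustment left 855 higher and 826 lower. Camera with an estimated correlation called 0 lists higher and 0 lower, and 7 without shControl replicate 3. Leaving out 1 array gave 4319 to 5573 probes higher, 4282 to 5821 lower, 2921 to 3186 at least 2-fold, 6 to 8 lists higher and 14 lower, and leaving out shControl replicate 3 gave the most probes. Same-numbered arrays deviated from their group means with correlations across probes of 0.0967, -0.0211 and 0.0878, against -0.0904 to 0.0981 for arrays of different numbers. The same-numbered array gave the highest value for shControl replicates 1 and 3 but not for 2, so these values do not settle whether the numbers pair the samples. With the replicate number as a block 4252 probes were higher and 4205 lower, and no named gene changed its call. The planned result for the targeted gene was not run. Detection on all 7 arrays left 11216 probes and 116 named genes, with 6 lists higher and 10 lower, and signal over background limits the rest. The lists that lost their camera call there were Fanconi anaemia and DNA damage checkpoint (adjusted p = 0.0505 each), luminal genes (0.110), the integrated stress response (0.0637) and hypoxia and glycolysis (0.102). Immune markers lost theirs as well, since their 3 genes left were too few for the list test. With no filter immune markers lost theirs (0.0727) and end joining gained one (0.0418). Array weights ended the calls of luminal genes (0.188), NRF2 targets (0.0591) and cytosolic ribosomal proteins (0.0721) and added inflammatory genes (0.00166), as leaving out shControl replicate 3 did, and median scaling ended that of cytosolic ribosomal proteins (0.586) and added inflammatory genes (0.00928). The cause was not tested.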

Other observations

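The tests of probe-specific signal and of chromosome 9 were chosen only after the result had been seen, and the lists of FOXO targets and lysosome genes were written after the genes with the largest rise had been seen but before the values of their members. Genes that are known as targets of FOXO transcription factors, such as PDK4 and FBXO32, were among those with the largest rise. Of 19 other measured FOXO targets 16 were higher and 0 lower in shBrit1, with a median log2 difference of 1.59. CITED2 rose by 3.03 (SE 0.08), TXNIP by 3.09 (SE 0.29), YPEL3 by 3.25 (SE 0.23) and FOXO1 itself by 2.95 (SE 0.11), while INSR differed by -0.09 (SE 0.10, adjusted p = 0.466). Of 25 lysosome genes 17 were higher and 2 lower, with a median of 0.93. The protease gene CTSF rose by 3.07 (SE 0.16), the autophagy receptor gene SQSTM1 by 2.38 (SE 0.22) and GAA by 2.24 (SE 0.11), and the proton pump subunit gene ATP6V1A was lower by a log2 difference of -0.66 (SE 0.14).

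A release of FOXO factors and a lysosomal gene programme are hypotheses for these rises. Each predicts that members not yet seen lie above most random lists of the same size and mean level. The median of the FOXO list lay above 100% of 10000 such lists, whose medians lay mostly between -0.41 and 0.42, and that of the lysosome list above 100% of 10000, mostly between -0.37 and 0.36. Both predictions were met, but random lists hold unrelated genes, so other genes that move together could meet them too. Cells that leave the cell cycle may raise the same genes, and protein activity was not measured.

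The count of changed probes was weighed against chance and against processing. Of the 35 splits of the 7 arrays into 3 and 4, only 1, the real one, gave as many as 9669 changed probes. By limma at an adjusted p under 0.05, the highest count among the others was 0. At an unadjusted p under 0.05 it was 5805, where 3 shBrit1 arrays were set against the rest, and the real split gave 10531. Every other split mixes the 2 groups, so a real difference between them widens its spread and lowers its count. As 1 in 35 is the smallest share that these splits can give, they do not exclude chance. Median scaling gave 9679 changed probes in all, which argues against equal distributions forced by normalization as the source of the count, and leaving out shControl replicate 3 gave 11394, which argues against that array. Differences between the 2 cell populations that do not come from Brit1, such as selection or a chip effect, stay open and were not tested, since each hairpin is represented by 1 set of cultures as far as the labels say.

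The third control array differed from the other controls by over 1 log2 on 431 tested probes upwards and 560 downwards, against 3 between controls 1 and 2. Its rises were led by IFI6 (5.19 above the mean of the other controls), SPRR2E (4.85), SAA1 (4.15) and CXCL2 (4.11), and its falls by MGP and PLAC8. Among 58 genes with a pair of bright probes of which 1 fell by over 1, the fallen probe had a median of -1.30 and its partner of -0.19, whereas for falls in shBrit1 the values were -1.33 and -1.16, so a probe-specific loss of signal may account for falls of this kind. For rises the partner's median was 0.29 against 1.35 over 54 genes, but only 6 had a pair of bright probes, too few to settle a gain on single probes. RNA of shBrit1 cells was argued against by 26 probes off on controls 1 and 2 and 3.48 higher in shBrit1, whose median there was 0.13. The 8 measured immune markers did not rise there as a set, with a median of 0.0248. Markers brought by immune cells on that array alone could not have passed the detection filter, and 12 were left out. This median therefore cannot decide on immune cells, and a state of that culture stays open too, untested.

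The fall of homologous recombination and Fanconi anaemia genes was weighed against a smaller share of cycling cells. The 17 members known to peak with the cell cycle had a median of -1.62 and the 25 others of -0.31. The difference of the means was -1.10 (permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). The permutation moved the classes over genes as if these were independent, so its p does not measure variation between cultures. Nor can it tell fewer cycling cells from lower expression of these genes within each cell. Fewer cycling cells may be a source of much of the fall, as 16 of 17 cycling members were lower. Among the 25 others 12 were lower, led by XRCC3 at -1.59, and 3 higher, so a part outside the cell cycle stays open. The mitosis and DNA replication lists were lower in 38 of 39 and 36 of 40 genes. Replication-dependent histone genes were higher in 12 of 17 cases and lower in 1. Whether the probes of these genes follow the share of cycling cells was not tested. The share of cycling cells itself was not measured.

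Genes of chromosome 9 were higher on shControl replicate 3, with a median of 0.25 over 508 genes against at most 0.10 on any other autosome. The largest median of any chromosome reached that value in none of 10000 permutations of genes over chromosomes (permutation p = 0.0001, the smallest they can give). The outermost 127 genes on the short arm had a median of 0.28, the outermost 127 on the long arm of 0.35 and the 254 between of 0.19. A gain of chromosome 9 in part of that culture is a candidate explanation, found and tested on the same array, and DNA copy number was not measured. Single probes failed rarely. On the whole array, 9 probes had a signal far below the background on shControl replicate 2 and 5 on replicate 3, one of them for RAB8A, whose signal was 3099 on shControl replicate 1, 11.2 on replicate 2 and 13.3 on replicate 3.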
